A study of Homo sapiens with 6 samples.

How the data were processed

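Gene expression was measured on 6 single-colour microarrays, each hybridised with Cy3-labelled complementary RNA from KG1a, an established human acute myeloid leukaemia cell line. Per the labels and the series' design text, all cells received 2 mM LiCl before irradiation with cobalt-60 gamma rays and a Bax antagonist peptide (BAP) afterwards, and the incubation lasted 48 h. The arrays fell into 2 groups by dose, 4 Gy and 8 Gy, with 3 replicates each. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The series as analysed here has no unirradiated arrays and no arrays without LiCl or BAP, and the comparison is therefore between doses only.

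The deposited scanner files hold spot intensities on a linear scale. Per the file headers, they were made with Agilent Feature Extraction version 11.5.1.1, which subtracted the background and removed spatial trends within each array, with no scaling between arrays. The authors also deposited a table of log2 values for the same arrays. Differences between arrays in that table matched log2 processed signals shifted to each array's 75th percentile, to within 0.02 for 99.13% of 50599 probes after a shift of each array. The table had a constant subtracted from each probe whose origin is unstated, so it carries no absolute level, and its column medians lay between -0.21 and -0.12. Direction is settled because a single colour was used. This table served as an alternative set of values.

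Each array held 62976 spots, of which 58717 were not controls. Spots flagged as outliers, 350 to 495 per array, were left out, and no spot was saturated. The processed signal was put on the log2 scale, the array's 75th percentile was subtracted, and spots of a probe were averaged. Of 50599 probes, 51 lacked a value on some array and were dropped. Probes well above background on at least 3 of the 6 arrays were kept, which left 28866 probes. The brightest of these represented each gene name, and 21828 genes were tested. Many gene names come from the array design and are old. A RefSeq table on assembly GRCh38.p14 was used for names only, and it matched 28174 probes by accession, 2618 by symbol and 620 by an older symbol, leaving 19187 unmatched. Probe coordinates are those of the files, on build hg19.

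Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists were compared with camera at a preset inter-gene correlation of 0.01, adjusted over 38 lists with at least 4 tested members. Camera with an estimated correlation and fry were run beside it. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 largest differences in each direction past the threshold with groups that do not overlap, up to 4 members with the smallest p from each list past camera's threshold or with at least 3 members past the gene threshold, and 20 fixed genes of apoptosis, p53, Wnt and the cell cycle. Some of the fixed genes are not reported here. A gene named outside this rule is said to be so. For different probes of a gene, differences are given where the probes disagree.

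All 6 arrays came from 1 slide and 1 scan. The 3 arrays at 4 Gy and 8 Gy replicate 1 lay in slide row 1, and 8 Gy replicates 2 and 3 in row 2, so the row was fitted as a block and row 1 was compared alone. The rows were not fully separable from dose, since row 2 held 1 group, and both row analyses compare 8 Gy replicate 1 alone with the 3 arrays at 4 Gy. The number of arrays limits the precision. Data were simulated with the mean and pooled spread of each of the 21828 genes, as independent noise of the same spread at both doses. The real median SD was 0.11 at 4 Gy and 0.17 at 8 Gy, so the simulated figures may not hold for the real arrays. With 200 genes changed, the gene test recovered 0.0% of genes changed 1.5-fold, 58.6% of those changed 2-fold and 88.3% of those changed 4-fold. False calls made up 4.9% of calls at 2-fold and 6.0% at 4-fold. Without any change, 0 of 20 simulated sets gave a called gene, and a list of genes simulated as independent and shifted 1.5-fold was called in 20 of 20.

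The alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the deposited log2 table, no filter on dim probes, probes above background on all 6 arrays, the mean of all probes of a gene, an intensity trend with robust eBayes, array weights, a replicate block, a slide row block, row 1 alone, a fold threshold, an unmoderated test and leaving out each array in turn. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.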

Results

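The data comprised 6 arrays of KG1a cells, a CD34-positive line from acute myeloid leukaemia, treated with LiCl and BAP and irradiated at 4 Gy or 8 Gy, with 3 arrays per dose. Lithium inhibits GSK3 kinases, which hold down Wnt signalling, and BAP is described in the series title as an antagonist of Bax, an effector of mitochondrial apoptosis. The series set out to study cell survival under this treatment, and the design allows the transcriptome at the higher dose to be compared with that at the lower dose. The share of probes well above background was 59.0%, 58.7% and 56.1% on the 4 Gy arrays and 58.2%, 53.8% and 53.4% on the 8 Gy arrays, in replicate order. The array's 75th percentile signal ranged from 330.2 to 464.1. Signals below are log2 values relative to that percentile, as mean ± SD with n = 3 per group unless stated, and differences are 8 Gy minus 4 Gy.

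At 8 Gy, replication-dependent histone genes, which supply the histones of new chromatin in S phase, fell as a group by camera with a preset correlation, but not with an estimated one (adjusted p = 0.218 with an estimated correlation). Of 55 tested members, 54 had a lower mean and 35 were lower when adjusted over the list alone, with a mean log2 difference of -0.39. HIST1H1E (current symbol H1-4), a linker histone, was 1.62-fold lower, at -0.39 ± 0.09 at 4 Gy and -1.09 ± 0.08 at 8 Gy. HIST1H4A (H4C1) was 1.59-fold lower, HIST1H2BG (H2BC8) 1.57-fold and HIST2H2AC (H2AC20) 1.44-fold, each with all 3 arrays at 8 Gy below all 3 at 4 Gy. The unfolded protein and integrated stress response list rose by a mean log2 difference of 0.15 (adjusted p = 0.519 with an estimated correlation). Among its members, ASNS, which makes asparagine, was 1.66-fold higher and PSAT1, an enzyme of serine synthesis, 1.59-fold. Genes of G2 phase and mitosis also rose as a list, by a mean log2 difference of 0.11 (adjusted p = 0.734 with an estimated correlation).

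None of these differences passed the threshold as single genes over the whole array. With limma, 0 of 21828 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.137. An unadjusted p under 0.05 was found for 1469 genes, 505 higher and 964 lower at 8 Gy, where chance gives 1091. The unmoderated test and limma with array weights also called 0 genes, while limma with an intensity trend and robust eBayes called 22 and limma on normexp-corrected signals 14. The groups did not overlap for 2983 genes, 13.7% of those tested, where chance gives 10%. Of these, 1282 were higher and 1701 lower at 8 Gy. The probe filter could keep genes that were above background at a single dose. On all arrays of a dose, 27239 probes were above background at 4 Gy and 25279 at 8 Gy. How much of either excess of lower genes comes from such dim genes was not tested. Because 0 genes passed over the whole array, the statements on gene groups below rest on the list tests and on counts adjusted over the list alone.

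**Figure D1:**
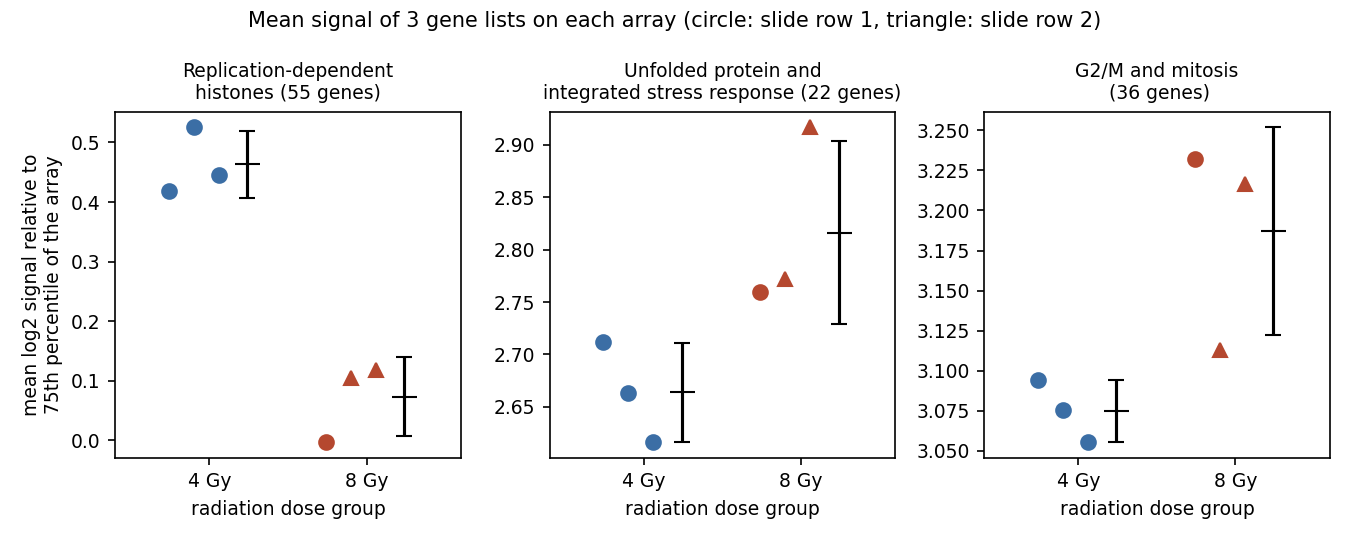
Mean log2 signal of 3 gene lists on each of the 6 arrays (vertical axis, relative to the array's 75th percentile), by dose group. Points are arrays, circles in slide row 1 and triangles in slide row 2, and bars show the group mean and SD of 3 arrays. The histone list lies between 0.42 and 0.53 at 4 Gy and between -0.0028 and 0.12 at 8 Gy.

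Camera placed the histone list lower at 8 Gy (adjusted p = 3.37e-31 over 38 lists), with list means of 0.46 ± 0.06 at 4 Gy and 0.07 ± 0.07 at 8 Gy. This call was lost at adjusted p = 0.218 with an estimated correlation, and fry gave an adjusted p of 0.0246. An unadjusted p under 0.05 was found for 37 members, all of them lower. The log2 difference of HIST1H2BG was -0.65 (SE 0.08, limma adjusted p = 0.312), that of HIST1H1E -0.70 (SE 0.09, adjusted p = 0.312), that of HIST1H4A -0.67 (SE 0.10, adjusted p = 0.327) and that of HIST2H2AC -0.53 (SE 0.08, adjusted p = 0.335). The probe of HIST1H1E lies on chromosome 6 from 26156928 to 26156987, and that of HIST2H2AC on chromosome 1 from 149858863 to 149858922 (hg19). A second probe of HIST1H4A gave -0.79 (SE 0.26). HIST1H2AC was the only tested member with a higher mean on its brightest probe (0.35, SE 0.26), and its 2 other probes gave -0.26 (SE 0.36) and -0.20 (SE 0.21), while under the alternative settings 51 to 55 members had a lower mean. Histone genes of a class are nearly identical in sequence, so probes can take up signal from other members and the genes are not independent. With slide row as a block, and within row 1 alone, the mean difference was -0.47. Row 2 held only 8 Gy arrays, so both values are the same contrast of 1 array, 8 Gy replicate 1, with the 3 arrays at 4 Gy, and they take that array to vary as the others do. The count adjusted over the list alone went from 35 to 11 without 4 Gy replicate 2 and to 19 without 4 Gy replicate 3, while the mean stayed between -0.41 and -0.35.

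**Figure D2:**
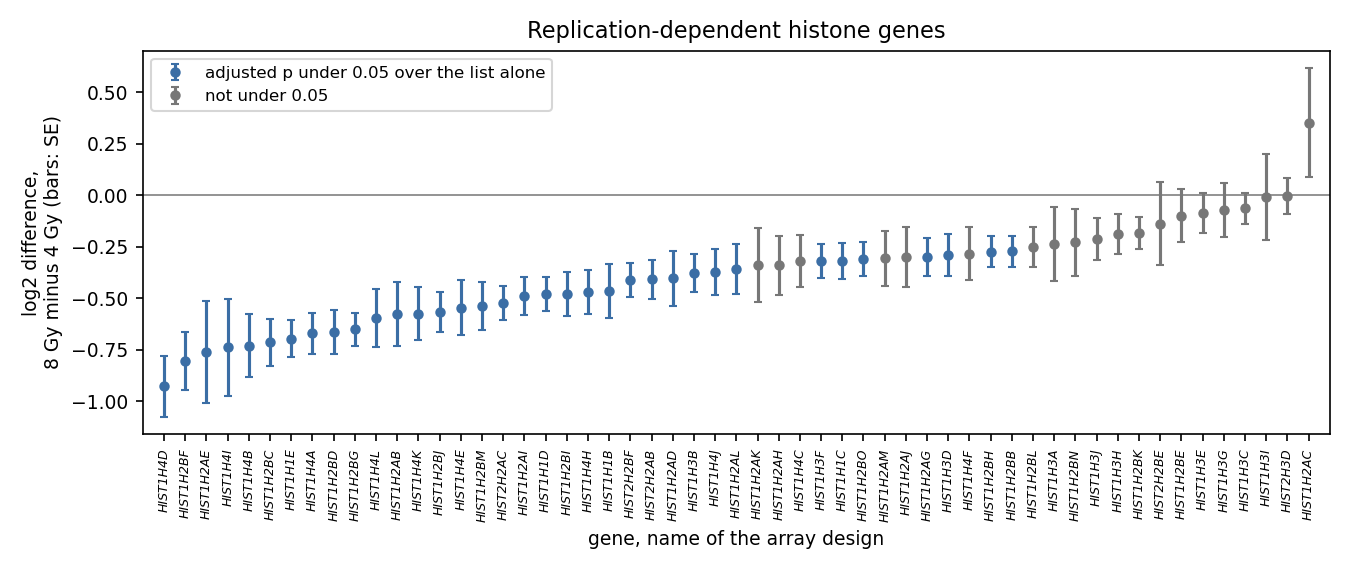
Log2 difference between 8 Gy and 4 Gy (vertical axis) for the 55 tested replication-dependent histone genes (horizontal axis), ordered by size, from 3 arrays per group. Bars are standard errors of the limma fit, and blue points are the 35 genes with an adjusted p under 0.05 over the list alone. On the brightest probe of each gene, all but HIST1H2AC lie below 0.

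The unfolded protein and integrated stress response list rose at 8 Gy, by a mean log2 difference of 0.15 (camera adjusted p = 9.35e-06), with list means of 2.66 ± 0.05 at 4 Gy and 2.82 ± 0.09 at 8 Gy. Of 22 tested members, 16 had a higher and 6 a lower mean, and 8 passed when adjusted over the list alone, 7 of them higher. The call was lost at adjusted p = 0.519 with an estimated correlation, and fry gave an adjusted p of 0.0480. ASNS was at 3.38 ± 0.01 at 4 Gy and 4.11 ± 0.03 at 8 Gy, a log2 difference of 0.73 (SE 0.07, limma adjusted p = 0.245). PSAT1 differed by 0.67 (SE 0.09, adjusted p = 0.312), and its second probe also by 0.67. SLC7A11, the cystine transporter subunit, differed by 0.56 (SE 0.07, adjusted p = 0.312). CHAC1, which degrades glutathione, differed by 0.58 (SE 0.08, adjusted p = 0.327), and by 0.29 on its second probe. The ASNS probe lies on chromosome 7 from 97481461 to 97481520 and that of SLC7A11 on chromosome 4 from 139085433 to 139085492 (hg19). For all 4 genes each array at 8 Gy lay above each array at 4 Gy.

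Other members higher when adjusted over the list alone, named here after their values were seen, were PHGDH, an enzyme of serine synthesis (0.51), TRIB3 (0.45) and SESN2 (0.41). SDF2L1, which acts in protein folding in the endoplasmic reticulum, went the other way at -0.84 (SE 0.22), with an SD of 0.46 over the 8 Gy arrays. The endoplasmic reticulum chaperones HSPA5 (-0.04, SE 0.08) and HSP90B1 (0.02, SE 0.13) differed by less than their standard errors on their brightest probes, but a second probe of HSP90B1 gave -0.31 (SE 0.11). The arrays of slide row 2, both at 8 Gy, had the fewest probes above background. With slide row as a block the list differed by 0.095 (camera adjusted p = 0.0220), and within row 1 alone it no longer passed (0.095, adjusted p = 0.0853). Both values again rest on 8 Gy replicate 1 alone against the 3 arrays at 4 Gy.

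**Figure D3:**
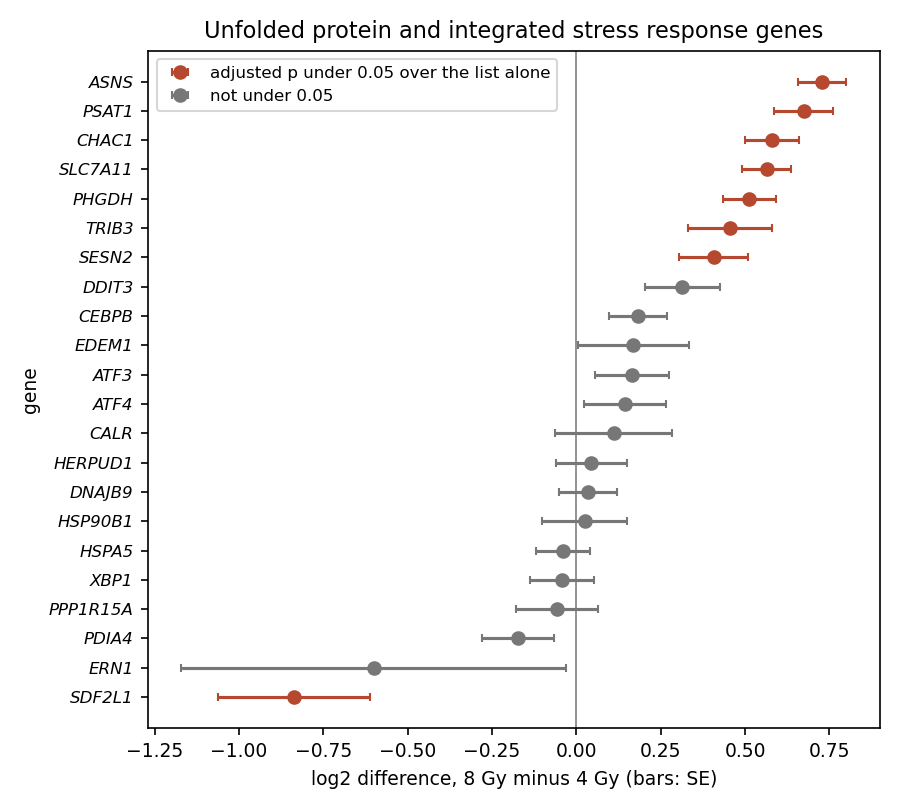
Log2 difference between 8 Gy and 4 Gy (horizontal axis) for the 22 tested genes of the unfolded protein and integrated stress response list (vertical axis), from 3 arrays per group. Bars are standard errors of the limma fit, and red points are the 8 genes with an adjusted p under 0.05 over the list alone. ASNS lies highest at 0.73 and SDF2L1 lowest at -0.84.

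Genes of G2 phase and mitosis rose as a list, by a mean log2 difference of 0.11 (camera adjusted p = 2.80e-05), with list means of 3.07 ± 0.02 at 4 Gy and 3.19 ± 0.06 at 8 Gy. Of 36 tested members 34 had a higher mean, but 0 passed when adjusted over the list alone, and limma gave 2 an unadjusted p under 0.05. The call was lost at adjusted p = 0.734 with an estimated correlation, and fry gave an adjusted p of 0.300. FOXM1, a transcription factor of the G2 programme, differed by 0.28 (SE 0.09, limma adjusted p = 0.627) and CDC25C, a phosphatase that activates CDK1, by 0.41 (SE 0.17, adjusted p = 0.739). AURKB, a mitotic kinase, differed by 0.28 (SE 0.12, and 0.16 without 8 Gy replicate 1) and NUSAP1, a spindle protein, by 0.19 (SE 0.08), both with an adjusted p of 0.752. CCNB1 (0.16, SE 0.09) and the proliferation marker MKI67 (0.12, SE 0.13, with 0.36 and 0.08 on its other probes) did not pass, and MKI67 showed no difference without 4 Gy replicate 1 (0.00) and 0.20 without 4 Gy replicate 2. The G1/S and DNA replication list did not pass camera (mean -0.062, adjusted p = 0.266, and 0.00439 by fry for a difference in either direction), with 22 of 34 members lower, though it passed on normexp-corrected signals (mean -0.0791, adjusted p = 0.00378, and adjusted p = 0.979 with an estimated correlation in the fit above). PCNA differed by -0.03 (SE 0.10), by 0.04 without 8 Gy replicate 1 and by -0.10 without 8 Gy replicate 3. It differed by -0.17 with slide row as a block. With slide row as a block, and within row 1 alone, the G2 and mitosis list differed by 0.16, again from that 1 array at 8 Gy, with 0.51 for AURKB, 0.62 for CDC25C and 0.099 for NUSAP1. None of the 3 camera calls held with an estimated correlation, under which 0 of 38 lists passed.

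None of the apoptosis genes given here, fixed in advance, passed the test between the doses. BAX was at 4.12 ± 0.11 at 4 Gy and 3.91 ± 0.34 at 8 Gy, a log2 difference of -0.21 (SE 0.18, limma adjusted p = 0.837) that was -0.02 without 8 Gy replicate 3. BAK1, the other effector, differed by -0.08 (SE 0.08), and the pro-survival genes BCL2 and BCL2L1 by 0.07 (SE 0.08) and -0.0011 (SE 0.09, from -0.07 to 0.05 when each array was left out). The second probe of BCL2 gave -0.04 (SE 0.13) and the mean of all its probes 0.02. BCL2 ranged from 0.04 to 0.10 when each array was left out. MCL1, a short-lived pro-survival protein, differed by -0.74 (SE 0.40, adjusted p = 0.788), and its 8 Gy arrays were far apart at 0.91, 0.10 and -0.77. The difference was -0.31 without 8 Gy replicate 3 and -1.16 without 8 Gy replicate 1. The BH3-only genes BBC3 (0.08, SE 0.12, but -0.03 without 8 Gy replicate 2) and PMAIP1 (0.19, SE 0.10) did not pass either. With slide row as a block, BAX differed by -0.07, MCL1 by 0.097, BBC3 by -0.0024 and PMAIP1 by 0.077. The lists of pro-survival BCL2 genes (mean -0.18, or -0.065 without 8 Gy replicate 3, 1 of 5 members higher, camera adjusted p = 0.787), pro-apoptotic BCL2 genes (0.0049, 4 of 9 higher, 0.952), caspases and apoptosome (-0.03, 7 of 21 higher, 0.933) and death receptors and ligands (-0.07, 6 of 14 higher, 0.933) were not past camera's threshold. Fry's mixed test asks whether members differ in either direction, and the death receptor list passed it (adjusted p = 0.0139). On normexp-corrected signals the mean of that list was -0.0086.

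The p53 target genes split evenly, with 15 of 29 tested members higher and 14 lower (camera adjusted p = 0.978, fry mixed 0.0350), and their mean (-0.05) and median (0.0036) differed in sign. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, was at a low signal, -4.33 ± 0.18 at 4 Gy and -4.73 ± 0.52 at 8 Gy. Its log2 difference was -0.40 (SE 0.26), or -0.13 without 8 Gy replicate 1 and -0.64 without 8 Gy replicate 2. MDM2 differed by -0.41 (SE 0.20, adjusted p = 0.776) on its brightest probe, or by -0.19 without 8 Gy replicate 1, and by -0.21, -0.12 and 0.17 on the other probes tested. With slide row as a block CDKN1A differed by -0.93 and MDM2 by -0.85, and on normexp-corrected signals CDKN1A by -0.03. Genes of double-strand break repair and damage signalling had a mean difference of 0.04 (23 of 34 higher, adjusted p = 0.267), and those of excision and mismatch repair -0.05 (-0.0027 without 8 Gy replicate 3, 9 of 23 higher, 0.978). The CDK inhibitor and arrest list had a mean of -0.08 (5 of 15 higher, 0.429).

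No Wnt or lithium-sensitive list or gene given here passed the test between the doses. GSK3B differed by 0.07 (SE 0.10) and CTNNB1, which encodes beta-catenin, by -0.15 (SE 0.14), but without 8 Gy replicate 1 by 0.0014 and -0.03. MYC differed by 0.10 (SE 0.11), from 0.04 without 8 Gy replicate 2 to 0.19 without 8 Gy replicate 1. With slide row as a block GSK3B differed by 0.20, CTNNB1 by -0.41 and MYC by -0.08. CCND1 was not well above background on any array and AXIN2 on only 1 array at 8 Gy, by 1 of its 2 probes, so neither was tested. Wnt and beta-catenin targets (mean -0.11, 5 of 14 higher, camera adjusted p = 0.933), Wnt pathway components (-0.06, 7 of 21 higher, 0.547) and inositol phosphate and lithium-sensitive enzymes (0.02, 3 of 11 higher, 0.978) were not past the threshold. On normexp-corrected signals the mean of the Wnt targets was -0.02. Mean and median of the lithium-sensitive list differed in sign. CD34, the progenitor marker of this line, differed by -0.05 (SE 0.13), but by -0.17 without 8 Gy replicate 1, 0.055 without 8 Gy replicate 3 and 0.19 with slide row as a block. The stem and progenitor list had a mean of -0.08 (5 of 18 higher, adjusted p = 0.391, 0.0450 with the mean of all probes, and adjusted p = 0.734 with an estimated correlation).

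Among immune and stress lists not past camera's threshold, MHC and antigen presentation came closest (mean 0.13, 15 of 19 higher, camera adjusted p = 0.0722). It passed in 3 alternative settings, namely the intensity trend with robust eBayes (0.0408), without 4 Gy replicate 1 (0.0268) and without 8 Gy replicate 2 (0.0167). These calls used the preset correlation, and the list had an adjusted p = 0.734 with an estimated correlation. Its mean was 0.07 on normexp-corrected signals. The type I interferon list had a mean of 0.05 (22 of 37 higher, 0.214, 0.00625 without 8 Gy replicate 2, and adjusted p = 0.979 with an estimated correlation). The mean was -0.02 for NF-kB targets (14 of 26 higher, 0.935, fry mixed 0.000570), -0.03 for other cytokines and chemokines (6 of 15 higher, 0.978) and -0.12 for immediate early genes (8 of 18 higher, 0.331, fry mixed 0.00140), or -0.03 for the latter on normexp-corrected signals. NRF2 and antioxidant genes had a mean of -0.01 (13 of 25 higher, 0.933, fry mixed 2.89e-05), heat shock genes -0.02 (7 of 14 higher, 0.952), autophagy and lysosome genes -0.0016 (15 of 29 higher, 0.952) and the senescence-associated list -0.09 (6 of 14 higher, 0.326, fry mixed 0.0436). On the brightest probe of each gene, only 1 NRF2 or antioxidant gene had an unadjusted limma p under 0.05, namely SLC7A11. SLC7A11 also belongs to the stress response list. The probes of GSR, named here outside the naming rule, disagreed in size. The brightest gave -0.08 (SE 0.08) and the other -0.54 (SE 0.09). Of the growth and metabolism lists, cytosolic ribosomal proteins had a mean of 0.05 (27 of 35 higher, 0.128). That list passed in 4 alternative settings, with array weights (0.0475), with slide row as a block (0.0436), without 4 Gy replicate 3 (0.0222) and without 8 Gy replicate 1 (1.48e-05), all with the preset correlation. It had an adjusted p = 0.979 with an estimated correlation. The mean was 0.04 for ribosome biogenesis and MYC targets (16 of 23 higher, 0.266), 0.0067 for oxidative phosphorylation (14 of 35 higher, 0.952), 0.01 for glycolysis and hypoxia (17 of 28 higher, 0.890, fry mixed 0.0371), -0.01 for cholesterol synthesis (9 of 21 higher, 0.978) and -0.0009 for the proteasome (14 of 25 higher, 0.978).

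Markers of cell types that a KG1a culture should not hold were not past camera's threshold. The mean difference was -0.11 for T and NK cell markers (4 of 16 higher, camera adjusted p = 0.233), -0.20 for B cell markers (-0.065 without 8 Gy replicate 1, 2 of 5 higher, 0.787), -0.14 for fibroblast and stromal markers (-0.041 without 4 Gy replicate 3, 2 of 7 higher, 0.978, fry mixed 0.0371) and -0.11 for epithelial and endothelial markers (0.048 without 8 Gy replicate 3, 2 of 8 higher, 0.933). It was -0.02 for erythroid markers (5 of 12 higher, 0.978) and -0.07 for megakaryocyte and platelet markers (4 of 10 higher, 0.933). The tested T and NK cell markers were not dim, with a list mean signal of 0.09 ± 0.03 at 4 Gy. Granulocyte and monocyte differentiation, which is not among these cell types, had a mean difference of 0.05 (10 of 20 higher, 0.978). Under the other scalings 10 of the 38 list means changed sign, 0 of them of the 3 lists past camera. On normexp-corrected signals the mean was 0.06 for fibroblast and stromal markers, 0.05 for erythroid markers, -0.08 for B cell markers and 0.0020 for megakaryocyte and platelet markers. When each array was left out in turn, the mean turned sign in 15 of the 35 lists not past camera. It turned or moved by more than 1.5-fold in 29 of them, against 0 of the 3 lists past camera. Means near 0 pass such a ratio easily, and the 3 lists were called for their shift. The contrast is therefore no test of these lists.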

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

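The count of 0 genes past the threshold was found under 17 of 20 alternative settings, including the fold threshold, which could only give 0. It became 14 with normexp background correction (7 higher, 7 lower), 22 with an intensity trend and robust eBayes (15 higher, 7 lower) and 2 among probes above background on all 6 arrays (2 higher, 0 lower), where fewer genes were tested (19127). The cause was not tested for any of these settings. The first 2 of them shared 10 genes, among them ASNS and PSAT1 and, outside the naming rule, JDP2 and SLC6A9. Leaving out each array in turn gave 0 genes throughout, 0 to 0 in each direction, from fewer arrays than the main fit. The count of 3 lists past camera became 0 with an estimated correlation and 11 with fry's mixed test, which asks another question, and ranged from 3 to 5 when each array was left out, 5 without 8 Gy replicate 2, where the type I interferon and MHC lists were added. No pairing by replicate number was seen. The correlations of deviations were 0.021, 0.018 and 0.038 for the same number and -0.081 to 0.07 for different numbers. Such values cannot show that the samples were unpaired. With a replicate block 0 genes and 3 lists passed, and the counts adjusted over the list alone became 34 for histone genes and 5 for stress response genes. The direction of the 3 lists held in the 16 settings that altered their means. The histone list ranged from -0.47 to -0.30, the stress response list from 0.095 to 0.19 (adjusted p from 5.11e-07 to 0.519) and the G2 and mitosis list from 0.089 to 0.16. The stress response list was 0.10 without 8 Gy replicate 3, and within slide row 1 it no longer passed, with fewer arrays and 1 at 8 Gy. Genes with an unadjusted p under 0.05 numbered 898 to 2781, with 908 without 4 Gy replicate 2, 898 without 4 Gy replicate 3 and 2340 without 8 Gy replicate 1. Of the 30 named genes measured, 5 passed in some setting, and 8 changed sign in some setting. Under other scalings the median gene differed by -0.0243 to 0.0214, against -0.0083 here. Signal over background limits dim genes such as CDKN1A, and 36316 genes were tested without the filter.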

Other observations

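The tests of slide row, of the S-phase share and of endoplasmic reticulum stress, and the amino acid and chaperone lists used below, were chosen after the main values were seen. The genes named in this paragraph and the next lie outside the naming rule and were picked after their values were seen. The smallest p-values of all genes belonged to JDP2, SLC6A9 and S100P, all higher at 8 Gy on each of 3 arrays. JDP2, a transcriptional partner of JUN, was at -0.03 ± 0.04 at 4 Gy and 1.01 ± 0.04 at 8 Gy, 2.06-fold higher (limma adjusted p = 0.137). SLC6A9, a glycine transporter, was 2.34-fold higher (adjusted p = 0.137), and S100P, a calcium-binding protein, 2.71-fold (adjusted p = 0.180). The log2 difference of SLC6A9 was 1.22 here and 0.75 on normexp-corrected signals. WARS, the cytosolic tryptophan tRNA synthetase, was 1.81-fold higher (adjusted p = 0.327). In 28 further genes of the amino acid response, listed from the known pathway before their own values were seen, 23 had a higher mean at 8 Gy and 0 passed when adjusted over the list alone. They included the arginine transporter SLC7A1 (1.38-fold), the alanine aminotransferase GPT2 (1.27-fold) and the alanyl tRNA synthetase AARS (1.24-fold), with limma adjusted p-values of 0.513, 0.627 and 0.611. The 8 other cytosolic tRNA synthetases had a mean log2 difference of 0.05, 7 of them higher, at percentile 86.4 of matched random lists and so inside their central 95%.

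In lists that did not shift as a whole, single members passed when adjusted over the list alone. FADD, the adaptor of death receptors, was 1.34-fold lower at 8 Gy, and of the NF-kB targets TNFAIP3 was 1.31-fold higher and IER3 1.35-fold lower. CTSG, a granule protease, was 1.64-fold higher, while ACTA2 was 1.43-fold higher. The G1/S cyclins CCNE1 (1.28-fold lower) and CCNE2 (1.36-fold lower) had unadjusted p-values of 0.0111 and 0.0106 in the limma fit, and did not pass over their list.

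The list mean of the histone genes was lower on all 3 arrays at 8 Gy than on any array at 4 Gy. Probe brightness is argued against, since the list mean of -0.39 lay at percentile 0 of 10000 random lists matched on signal, the lowest at -0.11. This speaks to brightness only, as the list was called for its shift and random lists do not carry the correlation among its members. Slide row and dose cannot be told apart here. In the row of the 4 Gy arrays, 8 Gy replicate 1 lay 0.42 below the lowest of them, whose range was 0.11, and the 8 Gy arrays of row 2 lay 0.11 above it, but this rests on 1 array. A lower share of S-phase cells may contribute and stays open, since the G1/S list mean was -0.0625, at percentile 2.2 of matched lists, but past camera's threshold only on normexp-corrected signals. A change in histone transcript processing or in the labelling of transcripts without a poly(A) tail was not tested. The 10 splits of the arrays are too few for a share under 0.05, and the real mean difference was 0.39 in size against 0.19 as the highest of the others.

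The stress response list rose at 8 Gy by camera with the preset correlation (adjusted p = 0.519 with an estimated correlation). Probe brightness is argued against, as the list mean lay at percentile 100 of matched random lists. This again speaks to brightness only, since the list was called for its shift. An endoplasmic reticulum stress response stays open, since the 10 chaperone and folding members went both ways (5 higher, 5 lower, SD 0.33). The largest differences were those of SDF2L1 (-0.84) and ERN1 (-0.60, SE 0.57, at a low signal), and the median was -0.0078. The mean of the 10 members, -0.13, lay inside the central 95% of matched lists (-0.15 to 0.11), so they did not rise as a set. The rise of the list lay in its 12 other members (mean 0.39, 11 higher, 1 lower), a split made after the main values were seen. An amino acid response is a candidate explanation that these values cannot settle. The 28 genes outside the list had a mean of 0.16, above the central 95% of matched lists (-0.07 to 0.05). Random lists do not carry the correlation among genes of a pathway, so that range can be too narrow. No test with an estimated correlation was run for the 28 genes. Slide row and dose cannot be told apart for the list or the 28 genes. Only 8 Gy replicate 1 shares the row of the 4 Gy arrays. It lay above the highest of them by 0.15 for the genes outside the list (4 Gy range 0.092) and by 0.048 for the list (range 0.095). The 10 splits are too few to give a share under 0.05 (0.15 for the real split, 0.12 as the highest other).

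The 8 Gy arrays differed more among themselves than the 4 Gy arrays, with an SD of the log2 difference between arrays of 0.45 to 0.49 against 0.29 to 0.34. Noise of dim probes is argued against, since in the brightest 7276 genes the median SD at 8 Gy was 2.0 times that at 4 Gy, against 1.40 in the dimmest. A shift shared by row 2 is argued against, since its 2 arrays differed from each other by 0.48. Noisier arrays in row 2 stay open, since 8 Gy replicate 1 differed from the 4 Gy arrays by 0.365 on average and the 2 arrays of row 2 by 0.402 and 0.454, and row 1 held 1 array at 8 Gy. Labelling and hybridisation noise stays open and is not argued against. Over 8 spike-in probes the ratio was 2.03, though those of 8 Gy replicate 3 lay 0.57 high together. Without such shifts the ratio was 1.63, the same to rounding as the 1.63 over all genes. The dose itself is open too and was not tested apart from these.

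For the counts, the 10 splits of the 6 arrays are again too few for a share under 0.05. The real split gave 0 genes past the threshold against 0 at most in the others, 1469 genes with an unadjusted p under 0.05 against 1531, and 3 lists past camera against 5.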
